A study of Homo sapiens with 10 samples.

How the data were processed

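PolyA RNA of K1 papillary thyroid cancer cells was sequenced in 10 libraries, 2 for each of 5 groups, after Trizol extraction and library preparation with a SMARTER mRNA-seq kit, per the labels' protocols. The FN1 knockdown was a selected single-cell clone, and the re-expression cells were made from it by lentivirus, per the series record. Genome builds GRCh38.p13 and hg38 are named in the submitters' processing notes. The aligner, the counting program and the annotation release were not given in the sources used here, and neither was the use of strand.

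Each library had a deposited table of read counts per gene and a deposited table of TPM, per the file headers. The deposited values were of the kind called an expected count, estimated reads per gene made by the authors without scaling to depth: 86.64% to 93.41% of a library's values were whole numbers and the rest had decimals. The deposited TPM summed to 1000000 per library within rounding. Counts were rounded to whole numbers for testing, since plain counts had been assumed in the design. Genes were given by NCBI Gene ID. The files came in 3 sets: control and FN1 knockdown libraries listed 16237 genes, re-expression libraries 16549, and ZMAT3 knockdown libraries 14574 and 14545, the last only where the value was above 0. All 10 files shared 13924 genes. Symbols came from the files and from a RefSeq table of assembly GRCh38.p14, used for names only, which matched 12825 of 12838 tested genes (99.9%) by Gene ID. Positions, GC content and length came from GENCODE on GRCh38, for 12788 genes (99.61%).

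Total counts ran from 14401672 to 18571271 per library. Share intervals are Wilson 95% intervals, and the floor is 3 counts per library. Of the 13924 shared genes, 12838 passed edgeR's filterByExpr by group at a count minimum of 10. Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood in 1 fit of all 10 libraries with 5 group means, which left 5 residual degrees of freedom. The common biological coefficient of variation was 0.1228. The contrasts were FN1 knockdown against control, each re-expression arm against the knockdown, the 2 arms against each other, and ZMAT3 knockdown against control, each with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Both arms against control were fitted the same way.

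The design, tests, gene lists, naming rule and first set of alternatives were chosen before the data were examined. The naming rule took FN1 and ZMAT3 in every comparison. Per comparison it took the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between groups. It also took 4 called members, by adjusted p, of each list that passed or had 5 or more called members, and of these the text gives some. Where leaving out a library ends a gene's call, that library is named. The 21 lists covered matrix proteins, integrins and focal adhesion, matrix proteolysis, mesenchymal state, epithelial state, thyroid differentiation, MAPK pathway output, TGF-beta response, YAP and TAZ targets, cell cycle, p53 targets, apoptosis regulators, FN1 exon splicing regulators, interferon response, NF-kB cytokines, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, immediate early and heat shock genes, other cell types and mitochondrially encoded genes. The last had fewer than 5 tested members and was not tested. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation, with which no list passed in any comparison.

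Overlaps, covariances and list shifts of comparisons that share libraries were set beside 10 simulations of unchanged groups against the same libraries. For the arms against control, 10 more kept the knockdown as measured and put both arms at the control level. Since unchanged groups leave few calls to share, 2 further sets of 10 shuffled the measured fold changes among genes in 20 classes of abundance: those of the arms and the ZMAT3 knockdown against control, or those of both arms against the knockdown. All simulations drew the noise of each library independently, without a difference shared by replicate number. The pipeline was tested on simulated data drawn for the comparison of the isoforms (12762 genes, 50 changed at each fold, all with a mean of at least 5 CPM). There edgeR recovered 14, 41, 50 and 50 genes at 1.5-, 2-, 4- and 8-fold with 8 false calls, DESeq2 29, 42, 50 and 50 with 29 false calls, and limma on TPM (12061 genes) 15, 39, 50 and 50 with 5 false calls. A shift of 0.4 in 25 cholesterol genes gave a camera adjusted p of 0.000276, and 0 of 19 other lists passed.

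Alternatives planned with the design were DESeq2 1.42.0 as the test, its size factors in edgeR, no filter on low counts, only the 4 libraries compared, the replicate number as a block, a change of at least 2-fold, each library left out in turn, and limma with trend on deposited TPM as log2(TPM + 1) for genes at 1 TPM or more in 2 libraries, as log2(TPM + 0.1), and without that filter. Added after seeing the data were a GC correction of each library (loess) with and without the block, a length correction, genes missing from some files taken as 0, leaving out both ZMAT3 knockdown libraries with and without the block, only genes of stable implied length (within 10% in all libraries), only genes with under 10% of exonic bases under exons on the other strand, and a contrast of both arms together against the knockdown. A library left alone in its group was assumed to vary like the other groups. Genes not listed in all 10 files were left out of the main test.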

Results

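Gene expression was measured by RNA sequencing of polyA RNA in K1, a cell line from a papillary thyroid cancer. The 10 libraries fell into 5 groups of 2. They were cells with a control hairpin (shRNA control), a single-cell clone with a hairpin against fibronectin (FN1 knockdown), knockdown cells given fibronectin with or without the EDB exon by lentivirus (EDB(+)FN1 and EDB(-)FN1 re-expression), and cells with less ZMAT3 (ZMAT3 knockdown). FN1 codes for fibronectin, a secreted matrix protein, and EDB is an exon that some of its transcripts skip. Total counts per library ran from 14401672 to 18571271: 18571271 and 18526890 in control replicates 1 and 2, 18049779 and 17961069 in the FN1 knockdown, 17571208 and 17676636 with EDB(+)FN1, 17427518 and 17707639 with EDB(-)FN1, and 14401672 and 14630621 in the ZMAT3 knockdown. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between samples. Counts were given per gene and were not resolved by exon, so the EDB exon itself was not measured. Wilson intervals and floors below cover counting error only, while intervals of fold changes come from the edgeR fit and include the spread between libraries. Each comparison set 2 libraries against 2 (n = 2 per group), an error after ± is the SE of a log2 fold change or the SD of CPM (counts scaled to a fixed library total), and "edgeR adjusted p" stands for edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12838 genes.

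FN1 (GRCh38 chromosome 2, 215360440 to 215436172) checked the labels. It stood at 41940 ± 2200 CPM in control, 2004 ± 77.8 CPM in the FN1 knockdown (4.78% of control), 2659 ± 29.7 CPM with EDB(+)FN1 (6.34%), 2897 ± 416 CPM with EDB(-)FN1 (6.91%) and 48820 ± 3630 CPM in the ZMAT3 knockdown (116%). FN1 took 3.999% of all counts in control replicate 1 (Wilson 95% interval 3.99 to 4.008) and 0.2073% in knockdown replicate 1 (0.2052 to 0.2094). FN1 fell by 4.39 ± 0.19 on the log2 scale in the knockdown, 20.9-fold (edgeR adjusted p = 8.62e-06). Adding EDB(+)FN1 moved FN1 by 0.41 ± 0.16 over the knockdown, 1.33-fold, with a 95% interval of 0.04 to 0.78 (edgeR adjusted p = 0.602). The change with EDB(-)FN1 was 0.53 ± 0.16, 1.45-fold, with an interval of 0.16 to 0.9 (edgeR adjusted p = 0.441). Neither passed in this fit. The rise with EDB(-)FN1 was called by DESeq2 (DESeq2 adjusted p = 0.00525, where the alternatives ran from 0.00525 to 1) and by edgeR in 2 alternatives added after the data were seen. Both arms stayed below control, at -3.98 ± 0.18 (edgeR adjusted p = 1.59e-05) and -3.86 ± 0.18 (edgeR adjusted p = 2.07e-05). In the ZMAT3 knockdown FN1 lay at 0.22 ± 0.16 from control (edgeR adjusted p = 0.313); on deposited TPM it was called at 0.65 (limma adjusted p = 0.0033, where the alternatives ran from 0.0033 to 1), with the median of all genes at 0.38. ZMAT3, an RNA-binding zinc-finger protein (chromosome 3, 179017223 to 179072279), fell by 1.82 ± 0.13 in its own knockdown, 3.53-fold, from 89.27 ± 0.622 to 25.32 ± 1.44 CPM (edgeR adjusted p = 6.62e-05). In the FN1 knockdown it fell by 0.53 ± 0.12, 1.44-fold (edgeR adjusted p = 0.0217). That call ended without control replicate 1 (edgeR adjusted p = 0.0674), control replicate 2 (0.0748) or knockdown replicate 2 (0.113). It also ended with only the 4 libraries compared (edgeR adjusted p = 0.0565), at a 2-fold minimum (1) and in the 3 TPM settings (limma adjusted p = 0.122, 0.122 and 0.149), where the alternatives ran from 0.00303 to 1.

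**Figure D1:**
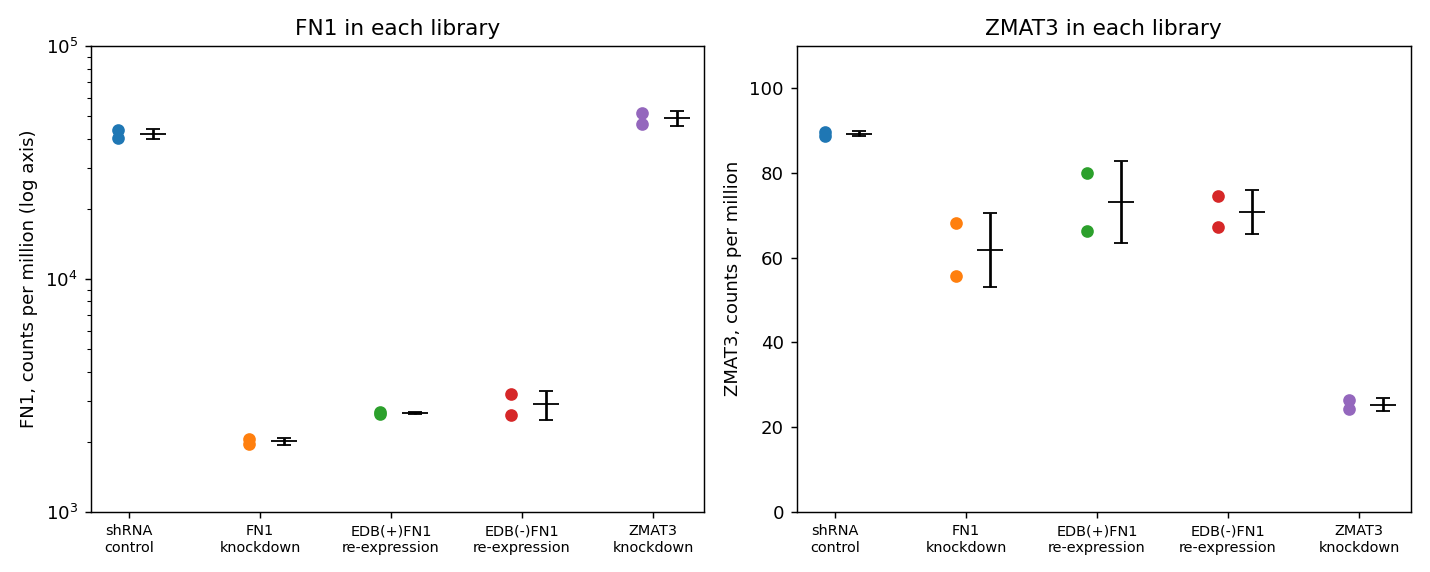
FN1 (left, log axis) and ZMAT3 (right, linear axis) in CPM, by group; points are libraries, and the line with its bar is the group mean with SD. FN1 stayed at 6.34% and 6.91% of control in the re-expression groups.

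The first comparison asked what differed between the FN1 knockdown and control. The knockdown was a single-cell clone, so traits of that clone and effects of less FN1 cannot be told apart. RSPO4, a secreted activator of Wnt signalling, rose by 3.78 ± 0.25 (13.7-fold, edgeR adjusted p = 6.95e-05), and PDGFB, a growth factor for stromal cells, rose by 2.99 ± 0.18 (7.97-fold, edgeR adjusted p = 4.54e-05). SORT1, a sorting receptor, rose by 2.83 ± 0.28 (7.1-fold, edgeR adjusted p = 0.000541). PHETA2, an endosomal adaptor, fell by 5.86 ± 0.47 (58-fold, edgeR adjusted p = 0.000172), GALNT5, a glycosyltransferase, fell by 3.83 ± 0.39 (14.2-fold, edgeR adjusted p = 0.000599), and SLFN11, a factor that blocks stressed DNA replication, fell by 3.81 ± 0.46 (14-fold, edgeR adjusted p = 0.00136). CLIP3 fell by 3.27 ± 0.3 and CD24 by 3.57 ± 0.54 (edgeR adjusted p = 0.000336 and 0.00342). FAM133A had 0 counts in both knockdown libraries against 6.61 ± 1.83 CPM in control, at least 40-fold lower at a floor of 3 counts per library (edgeR adjusted p = 0.000541).

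In all, 2070 of 12838 genes changed in the FN1 knockdown, 924 higher and 1146 lower, and 504 of these by more than 2-fold (202 higher, 302 lower). On deposited TPM the calls were 2357, of which 74.4% were higher, against 44.6% here, and the median of all genes then lay at 0.14. The count was 1338 without the ZMAT3 knockdown libraries and 812 with only the 4 libraries compared. The fit shares the spread over all groups, and the ZMAT3 knockdown replicates lay closer together (chi-square per degree of freedom 3.34, against 25.04 to 40.08 in the other groups). Leaving out 1 library lowered the count to 1211 without control replicate 1, 1202 without control replicate 2, 684 without knockdown replicate 1 and 1097 without knockdown replicate 2. Of the other genes with the largest changes, COL22A1 rose by 4.32 ± 0.85, ASTN1 by 3.99 ± 0.88, SAA1 by 3.14 ± 0.74 and BRINP2 by 2.8. Without knockdown replicate 1 their edgeR adjusted p was 0.0555, 0.0913, 0.115 and 0.3. Without control replicate 1 it was 0.0547, 0.063, 0.0845 and 0.115, and without control replicate 2 it was 0.072, 0.0994, 0.114 and 0.178. All 4 kept their direction there, at 3.1 to 4.88, 3.02 to 4.73, 2.37 to 3.43 and 1.4 to 3.22, the lowest each time without knockdown replicate 1. ERV3-1-ZNF117 rose by 3.71, and its call ended without control replicate 2 (edgeR adjusted p = 0.0698) or knockdown replicate 1 (0.0633). TMPRSS15 fell by 3.29 ± 0.64, a call that ended without knockdown replicate 1 (edgeR adjusted p = 0.072). SAA1 has the near-identical copy SAA2 and ERV3-1-ZNF117 is a read-through of neighbouring genes, so both are uncertain.

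**Figure D2:**
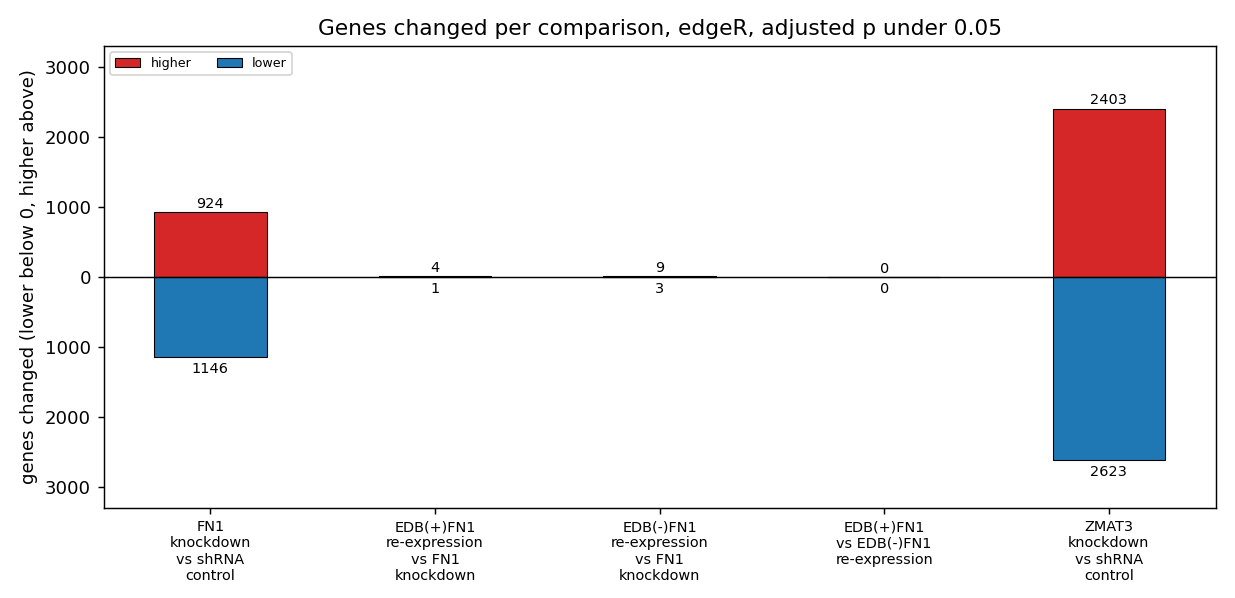
Number of genes changed in each of the 5 comparisons (edgeR, adjusted p under 0.05), with genes higher in the first group drawn above 0 and lower ones below. The bars run from 0 genes between the isoforms to 2403 higher and 2623 lower in the ZMAT3 knockdown.

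Among gene lists fixed before the data were examined, p53 targets and the unfolded protein response had the most members lower in the FN1 knockdown. Of 34 p53 targets, 12 fell, 0 rose and 22 did not pass; adjusted over the list alone 16 fell (camera adjusted p = 4.78e-08; adjusted p = 0.638 with an estimated correlation). TNFRSF10B, a death receptor, fell by 1.6 ± 0.12 (3.04-fold, edgeR adjusted p = 0.000104), and DDB2, a DNA damage sensor, fell by 2.11 ± 0.19 (4.33-fold, edgeR adjusted p = 0.000289). Of 31 unfolded protein response genes, 11 fell, 1 rose and 19 did not pass; adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 0.00019; adjusted p = 0.638 with an estimated correlation). PHGDH, an enzyme of serine synthesis, fell by 0.84 (1.79-fold, edgeR adjusted p = 0.00147), and HERPUD1, a factor of protein degradation at the endoplasmic reticulum, fell by 0.74 (1.67-fold, edgeR adjusted p = 0.00153). Both lists passed without each of the control and knockdown libraries in turn.

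Matrix lists were lower as well. Of 38 matrix proteolysis genes, 9 fell and 1 rose; adjusted over the list alone 11 fell and 3 rose (camera adjusted p = 0.00635; adjusted p = 0.638 with an estimated correlation). LOX, which crosslinks collagen, fell by 2.32 ± 0.12, 5-fold (edgeR adjusted p = 1.97e-05). Of 44 matrix proteins, 6 fell and 3 rose; adjusted over the list alone 10 fell and 3 rose (camera adjusted p = 0.0234; adjusted p = 0.638 with an estimated correlation). SPARC, a collagen-binding protein, fell by 1.77 ± 0.17 (3.42-fold, edgeR adjusted p = 0.000429) and EFEMP1, a fibulin, fell by 2.7 ± 0.34 (6.5-fold, edgeR adjusted p = 0.00159), while the laminin LAMA5 rose by 1.34 ± 0.15 (2.53-fold, edgeR adjusted p = 0.000863). Without knockdown replicate 2 both lists missed the threshold (camera adjusted p = 0.0657 and 0.109), and without control replicate 1 the matrix proteins did (0.145). With the GC correction, an alternative added after the data were seen, the matrix proteins missed it as well (camera adjusted p = 0.0563, where the alternatives ran from 0.00433 to 0.145).

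The calls of the other lists that passed each ended when any of 2 or 3 libraries was left out. Hypoxia and glycolysis genes (34; 4 fell, 2 rose, the same 4 and 2 adjusted over the list alone) were lower (camera adjusted p = 0.0301; adjusted p = 0.638 with an estimated correlation), among them the glycolytic enzyme PGAM1, which fell by 1.87 ± 0.13 (3.65-fold, edgeR adjusted p = 6.95e-05). Their call ended without control replicate 1 (camera adjusted p = 0.0596), control replicate 2 (0.0642) or knockdown replicate 2 (0.0657). Cholesterol synthesis genes (25; 4 rose, 1 fell, and adjusted over the list alone 6 and 1) were higher (camera adjusted p = 0.0197; adjusted p = 0.716 with an estimated correlation), with TM7SF2, a sterol reductase, up by 1.44 ± 0.22 (2.72-fold, edgeR adjusted p = 0.00369). That call ended without control replicate 2 (camera adjusted p = 0.178) or knockdown replicate 1 (0.5). NF-kB cytokines (38; 5 rose, 0 fell, the same 5 and 0 adjusted over the list alone) were higher (camera adjusted p = 0.0468; adjusted p = 0.782 with an estimated correlation), with IL32 up by 1.34 ± 0.18. Their call ended without control replicate 2 (camera adjusted p = 0.64), without knockdown replicate 1 (0.173) or with the GC correction (0.0552), where the alternatives ran from 0.00202 to 0.64. Interferon response genes (39; 4 rose, 1 fell, and adjusted over the list alone 2 and 0) were higher (camera adjusted p = 0.0468; adjusted p = 0.638 with an estimated correlation), a call that ended without control replicate 1 (camera adjusted p = 0.0565), control replicate 2 (0.0729) or knockdown replicate 2 (0.157), with the GC correction (0.0563) or with no filter on low counts (0.0723), where the alternatives ran from 0.00705 to 0.157. The remaining 12 lists did not pass. By camera adjusted p they were integrins and focal adhesion (0.253; 2 rose, 4 fell), mesenchymal state (0.377; 1 rose, 2 fell), epithelial state (0.441; 2 rose), thyroid differentiation (0.377; 1 fell), MAPK pathway output (0.825; 1 rose, 2 fell), TGF-beta response (0.172; 4 fell), YAP and TAZ targets (0.444; 3 fell), cell cycle (0.287; 3 rose), apoptosis regulators (0.836; 3 fell), FN1 exon splicing regulators (0.571; 2 fell), immediate early and heat shock genes (0.749; 3 rose, 2 fell) and markers of other cell types (0.836; none called). Counts adjusted over the list alone were the same for these lists, except integrins and focal adhesion (1 rose, 4 fell) and cell cycle (2 rose). MAPK pathway output had a median of 0.02 and a mean of -0.01, and apoptosis regulators a median of 0.06 with camera's direction down.

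The next comparisons set cells given each FN1 isoform against the knockdown cells. None of the 5 groups was knockdown cells given a lentivirus without FN1. Effects of the lentivirus and of the added FN1 therefore cannot be told apart. HAS2, which makes hyaluronan, rose by 2.86 ± 0.12 with EDB(+)FN1 (7.25-fold, edgeR adjusted p = 1.03e-05) and by 2.55 ± 0.12 with EDB(-)FN1 (5.87-fold, edgeR adjusted p = 2.75e-05), and both calls held without each library in turn. LSAMP, a neuronal adhesion molecule, rose by 1.65 ± 0.17 and 1.63 (edgeR adjusted p = 0.0142 and 0.0195). LRP5, a Wnt co-receptor, rose by 1.94 ± 0.24 and 1.78 ± 0.24 (edgeR adjusted p = 0.045 and 0.0429), and ESM1, a secreted proteoglycan, by 1.4 ± 0.14 and 1.14 ± 0.14 (edgeR adjusted p = 0.0132 and 0.0279). CGNL1, a junction protein, fell by 2.25 ± 0.23 and 2.05 ± 0.22 (edgeR adjusted p = 0.0132 and 0.0195). In this fit these were all 5 genes changed with EDB(+)FN1 (4 higher, 1 lower), against 960 at an unadjusted p under 0.05. DESeq2 called 87 genes with EDB(+)FN1 and 77 with EDB(-)FN1, and edgeR with the replicate number as a block called 164 and 161. The replicate 1 minus 2 differences of the knockdown and the arms correlated at 0.51 to 0.57, and the fit without the block counts what they share as spread. With EDB(-)FN1, 12 genes changed in the fit without that block (9 higher, 3 lower), against 1003 at an unadjusted p under 0.05. The other 7 were IGFBP5 (2.5 ± 0.3), HCLS1 (2.13 ± 0.29), IL13RA2 (1.8 ± 0.25), TIE1 (1.76 ± 0.24) and KCNAB2 (1.73 ± 0.17), which rose, and SYNDIG1 (-0.84 ± 0.11) and NNMT (-0.83 ± 0.1), which fell. These libraries and the knockdown ones came as separate sets of files, so the file set cannot be told apart from re-expression either.

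Most of these calls ended when 1 library was left out, each of them with any of 2 to 4 libraries. With EDB(+)FN1, leaving out knockdown replicate 1 ended the calls of LSAMP (edgeR adjusted p = 0.195), LRP5 (0.312), ESM1 (0.0548) and CGNL1 (0.0794). Leaving out EDB(+)FN1 replicate 1 ended those of LSAMP (0.0951), LRP5 (0.122) and CGNL1 (0.124), EDB(+)FN1 replicate 2 those of LRP5 (0.337), ESM1 (0.108) and CGNL1 (0.108), and knockdown replicate 2 that of LRP5 (0.118). With EDB(-)FN1, leaving out knockdown replicate 1 ended the calls of LSAMP (edgeR adjusted p = 0.16), LRP5 (0.291), ESM1 (0.144), CGNL1 (0.112), IGFBP5 (0.0662), HCLS1 (0.317), IL13RA2 (0.182), TIE1 (0.242), SYNDIG1 (0.289) and NNMT (0.18). Without knockdown replicate 2 the calls of LSAMP (0.051), LRP5 (0.146), HCLS1 (0.131), TIE1 (0.17), SYNDIG1 (0.0879) and NNMT (0.0879) ended. Without EDB(-)FN1 replicate 1 those of LSAMP (0.0908), ESM1 (0.0908), CGNL1 (0.137), IGFBP5 (0.116), HCLS1 (0.163), IL13RA2 (0.145), TIE1 (0.0708), KCNAB2 (0.0754), SYNDIG1 (0.179) and NNMT (0.163) ended. Without EDB(-)FN1 replicate 2 those of LSAMP (0.0577), LRP5 (0.149), ESM1 (0.149), CGNL1 (0.116), IGFBP5 (0.116), HCLS1 (0.149), IL13RA2 (0.149), TIE1 (0.149), KCNAB2 (0.0577), SYNDIG1 (0.151) and NNMT (0.149) ended. Fold changes in the fits that ended a call kept their direction. They were, with EDB(+)FN1, 1.41 to 1.55 for LSAMP, 1.77 to 2.1 for LRP5, 1.21 to 1.29 for ESM1 and -2.38 to -2.12 for CGNL1. With EDB(-)FN1 they were 1.51 to 1.74 for LSAMP, 1.39 to 1.78 for LRP5, 0.94 to 1.22 for ESM1, -2.23 to -1.88 for CGNL1, 2.06 to 2.59 for IGFBP5, 2.01 to 2.27 for HCLS1, 1.47 to 1.88 for IL13RA2, 1.44 to 2.02 for TIE1, 1.69 to 1.77 for KCNAB2, -0.92 to -0.75 for SYNDIG1 and -0.86 to -0.8 for NNMT. The EDB(+)FN1 count was 2 without knockdown replicate 1, 15 without knockdown replicate 2, and 2 without either EDB(+)FN1 library. The EDB(-)FN1 count was 3 without knockdown replicate 1 and 2 without either EDB(-)FN1 library.

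**Figure D3:**
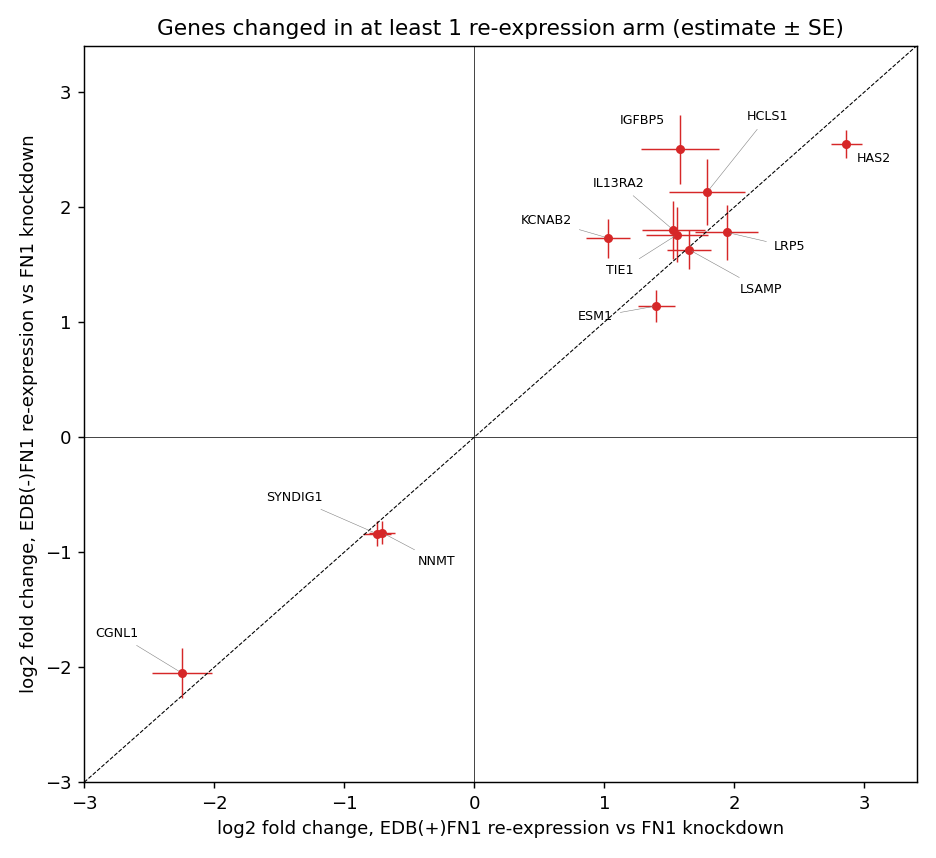
Log2 fold change over the FN1 knockdown with EDB(+)FN1 (horizontal) and EDB(-)FN1 (vertical) for the 12 genes changed in at least 1 of them; points are estimates with SE, and the dashed line marks equal change. HAS2 lies farthest out, at 2.86 and 2.55.

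All 5 genes called with EDB(+)FN1 were also called the same way with EDB(-)FN1, where independent lists would share 0.00304. Simulations against the same knockdown libraries, with the fold changes of both arms shuffled among genes of like abundance, called more genes (360 and 390), of which 17.4 were shared. They planted the measured fold changes, noise included, and added noise again, so their counts are no measure for 5 and 12 calls. Across genes, which are not independent replicates, the 2 sets of fold changes had a covariance of 0.124, against 0.047 in simulations of unchanged arms (r = 0.782 against 0.502) and 0.0475 with shuffled fold changes (r = 0.189). The 2 knockdown libraries could not be split, so part of the excess may come from that shared control. Both arms also shared the lentivirus step and the file set, which could give agreement as well. Genes called in the knockdown and called the opposite way on re-expression numbered 2 with EDB(+)FN1 (HAS2 and LSAMP) and 5 with EDB(-)FN1 (HAS2, LSAMP, IGFBP5, TIE1 and KCNAB2), where independent lists would give 0.429 and 1.02. In this fit, simulations of unchanged arms averaged 0.4 (0 to 3) and 0.1 (0 to 1), so the 2 lay within their range and the 5 above it. These simulations drew each library independently and so leave out the difference between replicate numbers that the groups shared. With the replicate number as a block, 69 and 60 genes were called the opposite way, where independent lists would give 23 and 22.7. Without the block, simulations with shuffled fold changes gave 59.6 of 360 called genes and 67.9 of 390, again no measure for so few calls. The count with EDB(+)FN1 was 1 without EDB(+)FN1 replicate 1 and 9 without knockdown replicate 2. The count with EDB(-)FN1 was 1 without either EDB(-)FN1 library and 3 without control replicate 1 or knockdown replicate 1. Against control, LSAMP lay at 0.22 and 0.2 (edgeR adjusted p = 0.379 and 0.429) and HAS2 above it at 1.88 and 1.57 (edgeR adjusted p = 2.96e-05 and 7.3e-05). Of the 2070 genes changed in the knockdown, 2050 (99.03%) and 2055 (99.28%) kept the sign of their difference from control with EDB(+)FN1 and EDB(-)FN1, and 1461 and 1417 were called the same way, where independent lists would share 184 and 172. These comparisons share the control libraries. Simulations with the knockdown as measured and both arms at the control level gave the same sign for 64.2% and 64% of the knockdown genes. Those with the arms' fold changes from control shuffled called more knockdown genes, 2670, and gave 406 and 414 called the same way. The 2 control libraries could not be split, so part of the excess may come from them. Both arms were also made from the knockdown clone, so differences that the clone carries would be kept in them.

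Several gene lists shifted the same way in both arms by camera, although edgeR called 0 members of any list in either. Both arms were set against the same 2 knockdown libraries, whose noise shifts lists the same way in both. In simulations of unchanged arms the list medians correlated at 0.39 on average (-0.158 to 0.826), against 0.874 here, and camera gave 13.4 lists the same direction in both arms (9 to 17), against 18 here. The simulations drew genes independently and so leave out noise shared by the genes of a list. Of the 6 lists that passed in both arms, 4 (unfolded protein response, p53 targets, cholesterol synthesis and interferon response) went opposite to the knockdown's shift from control, which such noise in the knockdown libraries would also give, and the libraries could not be split. Unfolded protein response genes lay higher as a list with EDB(+)FN1 (median 0.26, camera adjusted p = 1.73e-05; adjusted p = 0.372 with an estimated correlation) and with EDB(-)FN1 (0.31, 4.4e-10; adjusted p = 0.315 with an estimated correlation). Cholesterol synthesis genes lay lower (median -0.27, camera adjusted p = 1.9e-07; adjusted p = 0.372 with an estimated correlation, and -0.25, 4.14e-07; adjusted p = 0.409 with an estimated correlation). The p53 targets lay higher as a list (medians 0.15 and 0.2, camera adjusted p = 0.00111 and 7.29e-06; adjusted p = 0.372 and 0.315 with an estimated correlation), as did immediate early and heat shock genes (medians 0.15 and 0.19, camera adjusted p = 0.000237 and 1.25e-05; adjusted p = 0.26 and 0.315 with an estimated correlation). Interferon response genes lay lower (medians -0.23 and -0.18, camera adjusted p = 0.000237 and 0.00169; adjusted p = 0.26 and 0.315 with an estimated correlation), and so did matrix proteins (medians -0.15 and -0.15, camera adjusted p = 0.00193 and 0.00882; adjusted p = 0.26 and 0.315 with an estimated correlation), of which 2 members fell in each arm adjusted over the list alone. With EDB(+)FN1 and not with EDB(-)FN1, camera passed thyroid differentiation (median -0.16, camera adjusted p = 0.0169; adjusted p = 0.26 with an estimated correlation; 3 fell adjusted over the list alone) and epithelial state genes (median -0.26, camera adjusted p = 0.0229; adjusted p = 0.378 with an estimated correlation), both lower. With EDB(-)FN1 and not with EDB(+)FN1, it passed NF-kB cytokines (median 0.29, camera adjusted p = 0.0328; adjusted p = 0.859 with an estimated correlation) and MAPK pathway output (median 0.1, camera adjusted p = 0.0356; adjusted p = 0.587 with an estimated correlation), both higher. Set directly against each other, the arms differed for epithelial state genes (camera adjusted p = 0.00193, adjusted p = 0.725 with an estimated correlation), a call that ended without EDB(+)FN1 replicate 1 (camera adjusted p = 0.252) or EDB(-)FN1 replicate 2 (0.71). Thyroid differentiation missed the threshold there (camera adjusted p = 0.587). MAPK pathway output missed it (0.661) but passed without EDB(+)FN1 replicate 1 (0.00738) or EDB(-)FN1 replicate 2 (0.0125). NF-kB cytokines missed it in the main fit (0.1) and with no filter on low counts (0.101). They passed, lower with EDB(+)FN1, with only the 4 libraries compared (0.0236) and with the replicate number as a block (0.00164). Their direction followed the library left out. They lay lower with EDB(+)FN1 without its replicate 1 or EDB(-)FN1 replicate 2, and higher without EDB(+)FN1 replicate 2 or EDB(-)FN1 replicate 1. The cytokines lay higher in replicate 1 by a median of 0.88 with EDB(+)FN1 and 0.93 with EDB(-)FN1. Leaving out 1 library thus set their direction through the replicate number and could not decide on the isoforms. With both replicates of each arm kept, they lay lower with EDB(+)FN1 in the main fit, with only the 4 libraries compared and with the block. Whether this difference passed depended on the fit. The passes of MAPK pathway output may follow the replicate number too, since that list lay lower in replicate 2 across groups (median -0.13). So may the ends of the epithelial state call, since that list lay higher in replicate 2 (median 0.33), and the call held with the block. The remaining 12 lists in each arm did not pass, the nearest being TGF-beta response with EDB(+)FN1 (camera adjusted p = 0.0511) and thyroid differentiation with EDB(-)FN1 (0.0956). Adjusted over the list alone, TGF-beta response had 3 higher and 2 lower with EDB(+)FN1 and 1 higher with EDB(-)FN1, matrix proteolysis 2 and 1 higher, mesenchymal state 1 and 1 lower, and with EDB(-)FN1 thyroid differentiation 2 lower and p53 targets and MAPK pathway output 1 higher each. All other lists had 0.

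Several of these list calls also ended without 1 library, and that of epithelial state genes with EDB(+)FN1 ended with no filter on low counts (camera adjusted p = 0.0612, where the alternatives ran from 0.000304 to 0.619). With EDB(+)FN1, leaving out replicate 1 of that group ended those of the unfolded protein response (camera adjusted p = 0.253), p53 targets (0.253), immediate early genes (0.19), thyroid differentiation (0.19) and epithelial state (0.253). Leaving out knockdown replicate 2 ended those of interferon response (camera adjusted p = 0.0771), immediate early genes (0.0667), p53 targets (0.219), thyroid differentiation (0.131) and epithelial state (0.619), and knockdown replicate 1 that of cholesterol synthesis (0.217). With EDB(-)FN1, the cholesterol call ended without knockdown replicate 1 (camera adjusted p = 0.288), the interferon call without knockdown replicate 2 (0.0842), and the matrix protein call without knockdown replicate 1 (0.0981) or EDB(-)FN1 replicate 2 (0.109). MAPK pathway output missed without knockdown replicate 1 (camera adjusted p = 0.0714), knockdown replicate 2 (0.154) or EDB(-)FN1 replicate 1 (0.824). NF-kB cytokines missed without knockdown replicate 2 (camera adjusted p = 0.469) and pointed the other way without EDB(-)FN1 replicate 1 (0.0693).

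**Figure D4:**
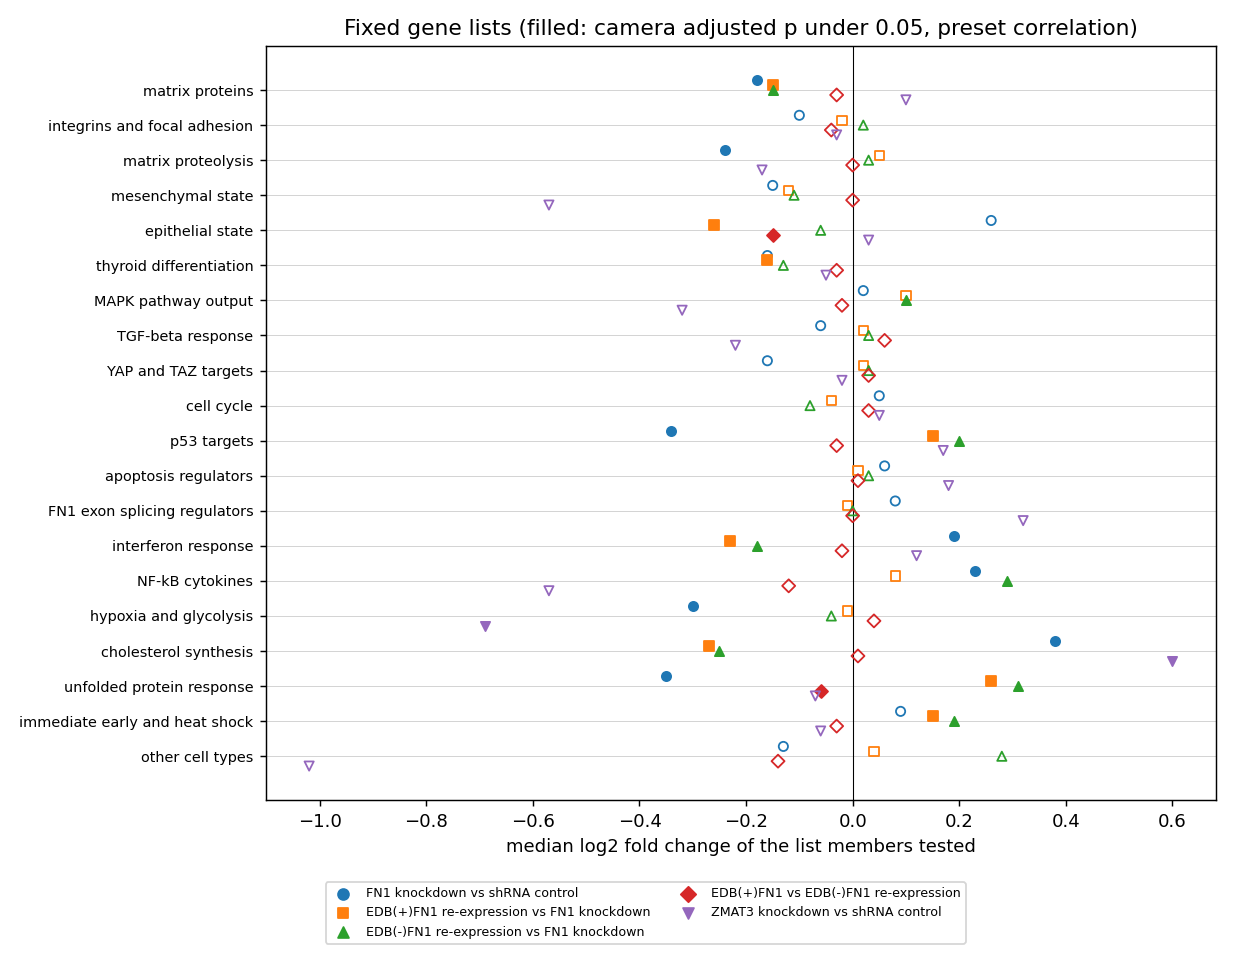
Median log2 fold change of each fixed list's tested members (horizontal) in the 5 comparisons, with filled symbols where camera with its preset correlation passed at 0.05. Unfolded protein response genes lie at 0.26 and 0.31 in the re-expression arms, and hypoxia and glycolysis genes at -0.69 in the ZMAT3 knockdown.

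The comparison of the isoforms with each other asked which genes differed between cells given FN1 with and without the EDB exon. FN1 stood at 6.34% of control with EDB(+)FN1 and 6.91% with EDB(-)FN1, against 4.78% in the knockdown, and neither rise passed in this fit. The EDB exon itself was not measured. A lack of calls here therefore cannot decide which genes depend on that exon. No gene passed: edgeR called 0 of 12838, and the smallest adjusted p was 1. An unadjusted p under 0.05 was found for 121 genes, fewer than the 642 expected by chance. With the replicate number as a block it was found for 228, still fewer, and 0 genes were called. DESeq2 called 1 gene and had 50 at an unadjusted p under 0.05, and limma on TPM called 0. The DESeq2 gene was BIVM-ERCC5 (-2.90 ± 0.43, DESeq2 adjusted p = 1.53e-07), a read-through of neighbouring genes that is uncertain and was named after its values were seen; edgeR gave -2.89 with an adjusted p of 1. HAS2 differed by 0.3 (95% interval 0.07 to 0.54), IGFBP5 by -0.92 (-1.54 to -0.31), KCNAB2 by -0.7 (-1.06 to -0.33) and FN1 by -0.12 (-0.49 to 0.24), each with an edgeR adjusted p of 1. For 11166 genes (87.04%) the 95% interval lay within a 2-fold change either way. In counts simulated for this comparison (12762 genes), the changed genes all had a mean of at least 5 CPM, and noise was drawn independently for each library. There edgeR recovered 14 of 50 genes changed 1.5-fold, 41 of 50 changed 2-fold and 50 of 50 changed 4-fold. Recovery of genes under 5 CPM was not measured. Epithelial state genes were lower with EDB(+)FN1 as a list (median -0.15, camera adjusted p = 0.00193; adjusted p = 0.725 with an estimated correlation), which ended without EDB(+)FN1 replicate 1 (camera adjusted p = 0.252) or EDB(-)FN1 replicate 2 (0.71). Unfolded protein response genes were lower (median -0.06, camera adjusted p = 0.0101, adjusted p = 0.841 with an estimated correlation). Without EDB(+)FN1 replicate 2 or EDB(-)FN1 replicate 1 they pointed the other way. This list also lay lower in replicate 2 than in replicate 1 across groups (median -0.18), so these turns may follow the replicate number. Epithelial state genes lay higher in replicate 2 (median 0.33), so the ends of their call may follow it too, and that call held with the replicate number as a block. The remaining 18 lists did not pass, and 0 members of any list were called, adjusted over all genes or adjusted over the list alone.

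The last comparison asked what changed in cells with less ZMAT3. EDARADD, an adaptor of ectodysplasin signalling, rose by 6.27 ± 0.34 (77.1-fold, edgeR adjusted p = 2.22e-05), PODXL, a surface sialomucin, by 3.55 ± 0.3 (11.7-fold, edgeR adjusted p = 9.25e-05), SORT1 by 3.23 ± 0.28 (9.36-fold, edgeR adjusted p = 0.000105) and the nucleotide receptor P2RY2 by 2.81 ± 0.51 (7.02-fold, edgeR adjusted p = 0.00263). ENTPD1, an ectonucleotidase, fell by 4.35 ± 0.18 (20.4-fold, edgeR adjusted p = 7.06e-06), CRMP1, a cytoskeletal adaptor, by 4.92 ± 0.38 (30.2-fold, edgeR adjusted p = 7.25e-05) and TIGIT, an immune receptor, by 4.8 ± 0.43 (27.8-fold, edgeR adjusted p = 0.000117). LRRC75A fell by 8.07 ± 0.55, 268-fold (edgeR adjusted p = 5.2e-05). The rule also named POTEE, ILDR2, SGK3 and OR2L2 among the genes that rose (by 5.43, 2.5, 2.45 and 2.41) and TREM1, TTN, GALNT15 and DEPP1 among those that fell (by -5.31, -4.39, -3.84 and -3.61). LRRC75A, TTN and DEPP1 have 12.2%, 15.5% and 23.3% of their exonic bases under exons on the other strand, counting is not stated to use strand, and POTEE has close paralogs, so these are uncertain.

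In all, 5026 genes changed in the ZMAT3 knockdown, 2403 higher and 2623 lower, of which 1181 by more than 2-fold (519 higher, 662 lower). On deposited TPM the calls were 7143, of which 87.2% were higher, against 47.8% here, and the median of all genes lay at 0.38. With only the 4 libraries compared, 5467 genes were called. The count was 3757 without control replicate 1, 4030 without control replicate 2, 2790 without ZMAT3 knockdown replicate 1 and 2502 without replicate 2. Genes called higher had a median GC content of 45.2% and those called lower 57.5%. No control library came in the set of files of the ZMAT3 knockdown, so that set and the knockdown cannot be told apart.

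Hypoxia and glycolysis genes were lower as a list in the ZMAT3 knockdown. Of 34, 23 fell, 1 rose and 10 did not pass; adjusted over the list alone 25 fell and 1 rose (median -0.69, and -0.27 on TPM; camera adjusted p = 1.16e-08; adjusted p = 0.546 with an estimated correlation). PFKL, a glycolytic kinase, fell by 1.23 ± 0.12 (2.35-fold, edgeR adjusted p = 0.000159), the peptide hormone ADM fell by 1.68 ± 0.19 (3.2-fold, edgeR adjusted p = 0.000293) and CA12, a carbonic anhydrase, fell by 2.03 ± 0.26 (4.09-fold, edgeR adjusted p = 0.000496). Of 25 cholesterol synthesis genes, 13 rose, 0 fell and 12 did not pass; adjusted over the list alone 14 rose (median 0.6; camera adjusted p = 0.000892; adjusted p = 0.858 with an estimated correlation). STARD4, a sterol carrier, rose by 1.15 ± 0.15 (2.22-fold, edgeR adjusted p = 0.000515), and HMGCS1, an early enzyme of the pathway, rose by 1.13 ± 0.19 (2.18-fold, edgeR adjusted p = 0.00195), although 15% of its exonic bases lie under exons on the other strand.

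No other list passed. Many held called members, but 5026 of all 12838 genes tested were called here. Of 37 FN1 exon splicing regulators, 16 rose and 3 fell, and adjusted over the list alone 17 and 5 (camera adjusted p = 0.0567). ZMAT3 itself is a member of this list and of the p53 targets, and counts among those that fell in both. The RNA-binding protein CELF1 rose by 0.79 ± 0.08 (edgeR adjusted p = 0.000235), and the splicing factors SRSF6 and SRSF10 rose by 0.89 ± 0.12 and 0.86 ± 0.12 (edgeR adjusted p = 0.000604 and 0.000818). Among p53 targets 12 rose and 4 fell (camera adjusted p = 0.338), with MDM2, which degrades p53, up by 1.13 ± 0.16 (edgeR adjusted p = 0.000773). Among cell cycle genes 11 rose and 3 fell (0.176), with the replication factor CDC6 up by 1 ± 0.12. Matrix proteins went both ways, 9 higher and 7 lower (0.338): the laminin LAMA5 rose by 1.96 ± 0.15 (edgeR adjusted p = 6.76e-05) and the collagen COL6A2 fell by 1.45 ± 0.16 (edgeR adjusted p = 0.000317). Matrix proteolysis genes (6 rose, 8 fell; 0.476) included LOXL1, which fell by 1.52 ± 0.16. Integrins and focal adhesion genes (5 rose, 13 fell; 0.439) included talin, TLN1, which fell by 0.74 ± 0.1, and mesenchymal state genes (1 rose, 9 fell; 0.177) the transcription factor TWIST1, which fell by 1.64 ± 0.22. TGF-beta response genes (2 rose, 5 fell; 0.338) included TGFB1, which fell by 1.4 ± 0.16, and immediate early and heat shock genes (6 rose, 7 fell; 0.556) included JUND, which fell by 2.42. The rest by camera adjusted p were apoptosis regulators (0.32; 9 rose, 5 fell), MAPK pathway output (0.32; 2 rose, 8 fell), thyroid differentiation (0.556; 2 rose, 4 fell), interferon response (0.719; 5 rose, 6 fell), NF-kB cytokines (0.338; 3 rose, 6 fell), YAP and TAZ targets (0.893; 2 rose, 4 fell), unfolded protein response (0.556; 1 rose, 4 fell), epithelial state (0.854; 2 rose, 1 fell) and markers of other cell types (0.338; 1 fell). Adjusted over the list alone the counts that differed were cell cycle (10 rose, 3 fell), integrins and focal adhesion (6 and 13), mesenchymal state (1 and 10), TGF-beta response (1 and 5), apoptosis regulators (10 and 6), interferon response (4 and 4), NF-kB cytokines (2 and 6), unfolded protein response (0 and 4) and epithelial state (2 and 0). Thyroid differentiation had a median of -0.05 and a mean of 0.08.

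Both knockdowns were set against the same control libraries, and 758 genes were called the same way in both (329 higher, 429 lower), where independent lists would share 407. Another 238 were called opposite ways, where independent lists would give 403. SORT1 and LAMA5 rose in both, and LOX fell in both, by 1.18 ± 0.11 in the ZMAT3 knockdown (edgeR adjusted p = 0.000166). Simulations against the same control libraries, with the fold changes of the ZMAT3 knockdown shuffled among genes of like abundance, called 2670 and 5100 genes. They gave 648 called the same way (619 to 685) and 454 called opposite ways (436 to 468). The measured calls were 2070 and 5026, so these counts cannot be set directly beside 758 and 238. With fold changes shuffled, more genes still went the same way than opposite ways, so the shared control can give part of the overlap. The covariance of fold changes across genes was 0.0853, against 0.0407 in these simulations (r = 0.176 against 0.069) and 0.0459 in those of unchanged groups (r = 0.501). The 2 control libraries could not be split, so part of the rest may come from them too. The difference between the isoforms, which shares no library with either knockdown, correlated across genes with the ZMAT3 knockdown at r = -0.022 and with the FN1 knockdown at r = -0.006.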

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

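Tests chosen only after the data were seen were those with missing genes taken as 0, the strand overlap, the file set of the ZMAT3 knockdown, all 3 for FN1 in the re-expression arms, the GC correction, and the stretches and the clone question for chromosomes; bounds for the GC correction and the chromosome 12 stretches were written before their own results were seen.

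Genes listed in only part of the files lay outside the comparisons. With absences taken as 0, 107 such genes entered the test. Of these, 13 were called in the FN1 knockdown (6 higher, 7 lower) and 54 in the ZMAT3 knockdown (6 higher, 48 lower), and 0 in the other 3 comparisons (edgeR, adjusted over all genes tested). The ZMAT3 knockdown files list only values above 0, so an absence there was read as 0 and not measured as one, and the calls share the limits of that file set.

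The ZMAT3 knockdown had 5026 changed genes, the most of the 5 comparisons. With each library's GC trend removed, 68.7% of them were still called the same way, which argues against GC content as the whole cause, although genes called higher had a median GC content of 45.2% and those called lower 57.5%. Overlap with exons on the other strand covered 13.9% of the genes changed at least 2-fold, against 13% of all genes, which argues against it as the main source, although it was 18.6% among those that fell and 7.8% among those that rose. A batch or file set of its own for these libraries cannot be told apart from loss of ZMAT3, because no control library was in that set. The chi-square per degree of freedom between its replicates was 3.34, below 25.04 to 40.08 in the other groups.

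FN1 stayed far below control in both re-expression arms. An introduced transcript that held only the coding part could lower the count, but the highest library reached 7.61% of the control mean, while coding bases make up 82.65% to 87.9% of the annotated transcripts compared. Scaling between libraries is argued against too, since FN1's highest share of raw counts in these arms was 8.29% of the control share. Low transcription of the introduced gene, silencing by the hairpin and a changed sequence that escapes counting cannot be told apart, because reads by exon or by sequence were not given; the larger rise over the knockdown was 1.45-fold. No biological explanation was tested.

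Genes on chromosome 12 lay lower in the FN1 knockdown, with a median 0.25 below that of all genes (-0.25, 95% bootstrap interval over genes -0.28 to -0.21, 679 genes). Other chromosomes shifted too: the medians lay at -0.15 on chromosomes 10 and 16, -0.13 on 4, 0.12 on 2 and 9, 0.13 on 15, and 0.15 on 13 and 21. Of stretches of 10 Mb, 9 of 9 on chromosome 16, 16 of 18 on 4 and 12 of 14 on 10 had a median below that of all genes, and the 11 stretches of chromosome 1 from 140 Mb on had medians of 0.25 to 0.45. Removing each library's GC trend with the replicate block left chromosome 12 at -0.26, which argues against GC content. On chromosome 12, 85.7% of 14 stretches (12 of 14) had a median below that of all genes, but the chromosome was picked for its shift, so this restates it. The first 3 stretches had medians of 0.11, -0.03 and 0.2, while those from 40 Mb on had -0.36 to -0.22, so the shift did not cover the whole chromosome. Chromosome 19 changed along its length too. Its stretches at 0 and 10 Mb had medians of 0.04 and 0.1, and those from 30 Mb on had -0.32 to -0.28. A lower copy number in the clone and a response to loss of FN1 cannot be told apart, since DNA was not measured, 1 clone was used and the EDB(+)FN1 cells made from it kept the shift at -0.24 against control. Over the whole of chromosome 1 the median against control lay at 0.08 in the knockdown, 0.08 with EDB(-)FN1 and 0.01 with EDB(+)FN1. Of its 23 stretches, 8, 8 and 10 lay below the median of all genes. The stretches from 140 Mb on were not looked at apart in the arms. EDB(+)FN1 lay below EDB(-)FN1 on this chromosome (-0.07, interval -0.08 to -0.06, with 22 of 23 stretches below the median of all genes). No explanation for this was tested.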

How the results depend on the processing

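Tests chosen only after the data were seen were the GC and length corrections, missing genes as 0, the fits without the ZMAT3 knockdown libraries, the contrast of both arms together and the subsets by implied length and strand overlap; the rest were planned. Of 166 values for named genes, all kept direction and side of the threshold with DESeq2 size factors, no filter and missing genes as 0, 163 with DESeq2, 149 with the GC correction, 161 with the length correction, 133 on log2(TPM + 1) and 93 at a 2-fold minimum. With only the 4 libraries compared 138 did. There the count fell from 2070 to 812 in the FN1 knockdown but rose from 5026 to 5467 in the ZMAT3 knockdown, so fewer samples alone do not account for it. The main fit shares the spread over all groups, and the ZMAT3 knockdown replicates lay closest together. Depth limits genes near the count minimum of 10, and 2 libraries per group limit changes under 2-fold. Where no reason is given, the cause was not tested.

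The replicate numbers were checked for pairing. The replicate 1 minus 2 differences correlated at 0.25 to 0.57 between the control, FN1 knockdown and re-expression groups. With the ZMAT3 knockdown they correlated at 0.08 to 0.13. Libraries of the 2 arms correlated at 0.9934 (both replicate 1) and 0.9944 (both replicate 2), against 0.9877 within EDB(+)FN1 and 0.9853 within EDB(-)FN1. The arms thus lay closer by replicate number than by group. This comes from the data, not the design: the labels do not say what the numbers mark, and 2 numbers are too few to decide that. With the replicate block the FN1 knockdown gave 3663 genes, EDB(+)FN1 164, EDB(-)FN1 161 and the isoforms 0 (228 at an unadjusted p under 0.05). Genes moved back numbered 69 and 60, where independent lists would give 23 and 22.7, and lists passing were 4 for the isoforms and 4 for the ZMAT3 knockdown. The block ended no call, neither of 166 named gene values nor of the 28 lists that passed without it, and it added lists. By camera adjusted p these were TGF-beta response (0.0488) and MAPK pathway output (0.0481) with EDB(+)FN1, TGF-beta response (0.0388) and NF-kB cytokines (0.00164) between the isoforms, and splicing regulators (0.0371) and NF-kB cytokines (0.0371) in the ZMAT3 knockdown. Between the isoforms, TGF-beta response then lay higher and NF-kB cytokines lower with EDB(+)FN1. Called members then included 5 and 5 lower for interferon response and 3 and 3 for matrix proteins in the arms, and 2 p53 targets higher with EDB(-)FN1. Both arms together gave 352 genes (125 higher, 227 lower) against 37. With the GC correction and the block the counts were 3667, 170 and 163, and moved back 68 and 60. Without the ZMAT3 knockdown libraries and with the block they were 3693, 158 and 143, and moved back 66 and 55. These 2 settings also called FN1 with EDB(-)FN1 (edgeR adjusted p = 0.0384 and 0.0269, where the alternatives ran from 0.00525 to 1).

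Below, counts are of genes changed, in the order EDB(+)FN1 and then EDB(-)FN1. DESeq2 gave 87 and 77 genes, 26 and 21 moved back, and 1 between the isoforms. With only the 4 libraries compared there were 812 in the FN1 knockdown, 1 and 1 in the arms, 1 and 1 moved back, and 4 lists passing in the ZMAT3 knockdown, among them splicing regulators (camera adjusted p = 0.0418) and mesenchymal state (0.0326). TGF-beta response and MAPK pathway output then passed with EDB(+)FN1 (camera adjusted p = 0.0306 and 0.0317), thyroid differentiation with EDB(-)FN1 (0.0433) and NF-kB cytokines between the isoforms (0.0236). A minimum of 2-fold left 504 in the FN1 knockdown, 1181 in the ZMAT3 knockdown and 1 moved back with EDB(+)FN1. On log2(TPM + 1) EDB(+)FN1 gave 2 genes with 1 moved back, on log2(TPM + 0.1) 8 with 4 moved back (8 with EDB(-)FN1), and without the TPM filter 3 with 1 moved back (7 genes with EDB(-)FN1). HERPUD1 in the ZMAT3 knockdown turned from -0.33 to 0.1 in all 3 TPM settings, where the median of all genes lay at 0.32 to 0.43. Genes of stable implied length gave 3 with EDB(+)FN1 and 1 moved back. Without the ZMAT3 knockdown libraries there were 1338 in the FN1 knockdown, 5 with EDB(-)FN1 and 3 moved back with EDB(-)FN1. The GC correction left 5 lists passing in the FN1 knockdown, without matrix proteins (camera adjusted p = 0.0563), interferon response (0.0563) and NF-kB cytokines (0.0552). It added TGF-beta response (0.031) and MAPK pathway output (0.0449) with EDB(+)FN1 and matrix proteins (0.0293) in the ZMAT3 knockdown, and gave a correlation of -0.039 between the isoform difference and the ZMAT3 knockdown.

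With 1 library left out, the FN1 knockdown ran from 684 to 1211 genes, EDB(+)FN1 from 2 to 15, EDB(-)FN1 from 2 to 10 and the ZMAT3 knockdown from 2502 to 4030; the isoforms gave 0 each time. Moved back ran from 1 to 9 and from 1 to 5. The correlation of the isoform difference ran from -0.072 (without EDB(-)FN1 replicate 2) to 0.083 (without EDB(+)FN1 replicate 2) with the FN1 knockdown, and from -0.042 (without EDB(+)FN1 replicate 1) to 0.019 (without EDB(-)FN1 replicate 2) with the ZMAT3 knockdown. Lists passing ran from 4 (without control replicate 2 or knockdown replicate 2) to 6 in the FN1 knockdown. With EDB(+)FN1 they were 3 without knockdown replicate 2, 4 without EDB(+)FN1 replicate 1 and 14 without its replicate 2, and with EDB(-)FN1 they ran from 5 (without knockdown replicate 1) to 9. Between the isoforms they were 8 and 4 without EDB(+)FN1 replicates 1 and 2, and 4 and 6 without EDB(-)FN1 replicates 1 and 2. In the ZMAT3 knockdown they ran from 2 to 5 (without control replicate 2). Camera adjusted p ran from 1.43e-08 to 0.469 for NF-kB cytokines with EDB(-)FN1, which pointed the other way without EDB(-)FN1 replicate 1 (0.0693). It ran from 6.59e-10 to 0.545 for the unfolded protein response between the isoforms, which did so without EDB(+)FN1 replicate 2 (0.197) or EDB(-)FN1 replicate 1 (0.545).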

Other observations

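The tests here were all chosen after the data were seen. Libraries with replicate number 2 differed from those with number 1 across groups, which belongs to no comparison of the report. In a fit with the replicate number as a term, edgeR called 1132 genes (499 higher and 633 lower in replicate 2). Of 38 NF-kB cytokines, 28 were lower in replicate 2 and 0 higher (median -0.63, camera adjusted p = 4.64e-37). By camera, 6 other lists passed: unfolded protein response (median -0.18, camera adjusted p = 0.000176), matrix proteolysis (-0.09, 0.000294), cholesterol synthesis (-0.21, 0.000301), MAPK pathway output (-0.13, 0.00116) and markers of other cell types (-0.54, 0.00116) were lower in replicate 2, and epithelial state (0.33, 0.0101) was higher. The report's comparisons call several of these lists too, and where such a call ended without 1 library, that may follow the replicate number. IL6, an inflammatory cytokine, fell by 1.05 ± 0.1 in replicate 2 against replicate 1 libraries (edgeR adjusted p = 0.00056), CXCL8, which attracts neutrophils, by 0.97 ± 0.1 (edgeR adjusted p = 0.00104), CCL20 by 1.64 ± 0.17 (edgeR adjusted p = 0.000909) and TNFAIP6 by 2.41 ± 0.28 (edgeR adjusted p = 0.00179). The median of the list was higher in replicate 1 by 0.64 in control, 0.52 in the FN1 knockdown, 0.88 with EDB(+)FN1, 0.93 with EDB(-)FN1 and 0.33 in the ZMAT3 knockdown. The labels do not say what the numbers mark, and no explanation was tested.

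The contrast of both re-expression arms together against the FN1 knockdown gave 37 genes (18 higher, 19 lower; edgeR), against 1293 at an unadjusted p under 0.05.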
